A study of Mus musculus with 29 samples.

How the data were processed

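Chromatin immunoprecipitation and sequencing was done in RAW264.7 cells, with 29 samples described in the labels. Peak lists were used for 26 of them, 25 of 7 histone marks and 1 of PU.1. The 3 input samples have no list here. There is 1 library per mark and condition, and the conditions are untreated, LPS for 1 h, LPS for 4 h, flavopiridol for 1 h and flavopiridol for 1 h then LPS for 4 h. Reads were aligned with Bowtie 1.0.1 to mm9 and peaks were called with MACS2, per the submitters' processing notes. The MACS2 version, the call settings, the control library, any pooling and the number of reads are not given in the sources used here, so the depth of each sample is unknown.

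The deposited histone lists are broad peaks and the PU.1 list holds narrow peaks with summits. The fold enrichment of each peak is a ratio over the caller's background, as the authors deposited it. The −log10 p and −log10 q of each peak are also the authors' deposited values. The deposited score is the whole part of 10 times the −log10 q, as found from the values. The lowest −log10 q deposited for a broad peak was 0.352. The authors also deposited 4 segmentations that name a chromatin state per interval in steps of 200 bp, 1 with 18 states and 3 with 27 states. The segmentation tool is not given in the sources used here.

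The deposited values of the broad peaks agreed less between lists than their widths did. Over 14 comparisons of an LPS list with the untreated list of the same mark, the widths of overlapping peaks correlated across peaks with a Spearman rho of 0.584 to 0.949, and the fold enrichments with 0.0479 to 0.416. Among the first 25 untreated peaks of each chromosome the fold enrichment rho was 0.221 to 0.823, and after peak 400 it was 0.0377 to 0.331. Width and fold enrichment correlated at 0.791 for PU.1 and at 0.0845 or less for each histone mark in untreated cells. Peaks are not independent replicates, and the cause was not tested. Intervals of the histone lists were used throughout. At LPS 4 h, peaks with a −log10 q of at least 5 were 32.5% of H3K36me2 peaks and covered 113 of 348.8 Mb. For H3K27me3 they were 11.7% of peaks and covered 42.5 of 424.8 Mb. Their share of the length was thus about their share of the peaks. Which peaks the threshold removes was not tested further, so values under it are not a check on strong peaks.

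Peaks on chromosomes 1 to 19 and X were used. The PU.1 list has 107986 lines and 99588 distinct intervals. Regions were compared by an overlap of at least 1 bp. A gained peak is one of the LPS list with no overlap in the untreated list, a lost peak is one of the untreated list with no overlap in the LPS list, and the rest are kept. Distal regions are H3K4me1 peaks without an overlapping H3K4me3 peak of the same condition. Shared length was compared with 1000 circular shifts of the second list along each chromosome. Gained regions were compared with 1000 draws of kept regions matched by decile of width and decile of fold enrichment, and since fold values agreed less between lists than widths did, strength is not counted as matched. Agreement between marks is the log2 odds ratio of gains and losses at overlapping places, against 1000 permutations within chromosomes. Alternatives used 100 shifts and 200 permutations, and every random step had seed 1. Shares have 95% Wilson intervals, which cover counting error only. No p-value was computed, since no condition has replicates, and depth sets how many peaks are called. State numbers were compared across conditions by 200 bp steps after each number was found closest in mark profile to itself. The 18-state segmentation was described only by its mark profile and enters no comparison.

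The main comparisons, most alternatives and the rule for named regions were chosen before the data were examined, and tests chosen after are named with their results. The rule for named regions took, per mark and time, the gained and the lost peak with the highest fold enrichment, with the 5 strongest distal H3K4me1 gains that overlap an H3K27ac gain, the 5 strongest PU.1 peaks and, for flavopiridol, the 3 strongest gains present and absent with the drug per mark. Since the fold values of broad peaks agreed less between lists than widths did, the histone regions named in the results are the widest in place of the strongest, which was decided after the values were seen. PU.1 peaks are ranked by fold enrichment as planned. Coordinates are 1-based mm9 positions. No gene annotation of mm9 was used here, so regions are not assigned to genes and the planned gene lists were not run.

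The alternatives tried were a −log10 q of at least 5, at least 50% of a peak covered, equal numbers of peaks by −log10 p, peaks merged within 1 kb, all sequences, no H3K4me3 within 2 kb, matching on width only, base pairs in place of peaks and segments of at least 400 bp. Peaks of at least 1 kb and equal numbers by width were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The matched draws were tested on simulated data over the 73217 H3K4me1 peaks of LPS 4 h, where 10 planted percentage points were found as 9.57, and −0.297 was found where none was planted. The agreement of gains and losses was tested over 15296 simulated regions, where a planted log2 odds ratio of 4 was found as 3.98 and random changes gave −0.02.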

Results

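Chromatin of RAW264.7 cells, a mouse macrophage-like line transformed by the Abelson leukaemia virus, was profiled by chromatin immunoprecipitation and sequencing. The histone marks were H3K4me1, H3K4me3, H3K27ac, H3K36me2, H3K36me3, H3K79me2 and H3K27me3, each in untreated cells and after 1 h or 4 h of lipopolysaccharide (LPS) at 100 ng/ml. LPS is a bacterial cell wall component that activates macrophages through Toll-like receptor 4. H3K4me1 and H3K36me2 were also profiled after 1 h of flavopiridol, an inhibitor of the kinase CDK9 that blocks transcription elongation, alone and followed by LPS for 4 h. PU.1, the lineage-determining transcription factor of macrophages, was mapped in untreated cells only. The series has 29 samples, of which 26 have a peak list and 3 are input chromatin without one, with 1 library per mark and condition. No spread between cultures can be measured, no p-value is given, and each difference is between single libraries. Intervals are 95% Wilson intervals and cover counting error only. Read depth is unknown, since the peak lists carry no read totals.

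H3K4me1, H3K4me3 and H3K27ac peaks covered less of the genome after 1 h of LPS than before and more after 4 h, while H3K36me2, H3K79me2 and H3K27me3 covered more at each time. H3K4me1, a mark of enhancers and of promoter flanks, covered 192.1 Mb in untreated cells, 176.3 Mb at 1 h and 200.4 Mb at 4 h. H3K27ac, found at active enhancers and promoters, covered 83.6, 73.1 and 90.7 Mb in the same order, and H3K4me3, the promoter mark, 38.3, 37.9 and 41.4 Mb. H3K36me2 went from 281.1 Mb to 320.5 and 348.8 Mb, and H3K27me3, the mark of Polycomb repression, from 362.5 Mb to 380.5 and 424.8 Mb. H3K79me2, which lies over the start of transcribed genes, covered 101.3, 107.8 and 110.8 Mb, and H3K36me3, a mark of transcribed gene bodies, 248.2, 250.5 and 242.2 Mb. The share of H3K36me2 peaks with a −log10 q of at least 5 was 9.02% in untreated cells, 22.6% at 1 h and 32.5% at 4 h, and for H3K27me3 it was 12.4%, 12.2% and 11.7%. For H3K4me1 it was 54.4%, 48.2% and 53.0%, for H3K27ac 81.9%, 76.9% and 79.2%, and for H3K4me3 90.0%, 89.6% and 91.3%. With single libraries, the lower length of these marks at 1 h cannot be told apart from weaker detection. Peaks with a −log10 q of at least 5 alone covered 40.3, 40.7 and 42.5 Mb for H3K27me3 and 19.4, 66.4 and 113 Mb for H3K36me2. Mean peak width in untreated cells was largest for H3K36me3, at 8779 bp, followed by H3K79me2 at 7531 bp, and was 1766 bp for H3K4me3.

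**Figure D1:**
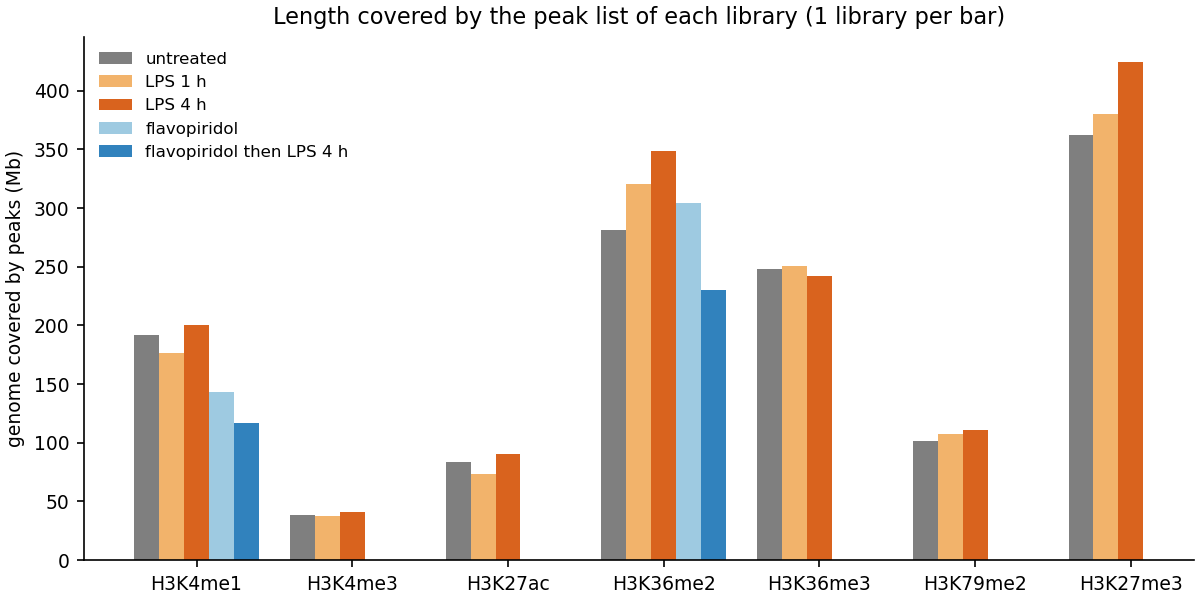
Genome length covered by the peaks of each library, in Mb, by histone mark; each bar is 1 library, coloured by condition, with no error bar since there are no replicates. H3K36me2 covered 281.1 Mb in untreated cells and 348.8 Mb after 4 h of LPS, but 230.0 Mb with flavopiridol then LPS.

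The LPS time course asks which marked regions appear and disappear after stimulation. At 4 h, gained peaks outnumbered lost ones for each histone mark except H3K36me3. H3K27ac gained 7402 peaks (21.3% of the 4 h list, 95% interval 20.9 to 21.7) and lost 4051 (12.9% of the untreated list, 12.5 to 13.2). H3K4me1 gained 11004 peaks (15.0%) and lost 4292 (6.55%), and H3K4me3 gained 2142 (9.64%) and lost 1420 (6.55%). At 1 h the order was the other way round for these marks: H3K27ac gained 2613 and lost 5902 peaks, H3K4me1 gained 4767 and lost 7006, and H3K4me3 gained 1203 and lost 1701. H3K36me2 gained 9877 and lost 4415 peaks at 1 h, and gained 11775 and lost 3057 at 4 h. Its lists still shrank, from 50867 peaks to 48312 at 1 h and 46696 at 4 h, while mean width went from 5526 to 7470 bp at 4 h. H3K27me3 gained 20715 and lost 6284 at 4 h, after 11916 and 9068 at 1 h. H3K79me2 gained 2647 and lost 1179 at 4 h, and H3K36me3 gained 3319 and lost 4050. The H3K36me3 list nevertheless grew from 28272 to 28970 peaks, so the order of gains and losses is not a change in peak number. Gained peaks were narrow: the median width of those of H3K4me1 at 4 h was 642 bp, against 1909 bp for the rest of that list. With equal numbers of the widest peaks in each list the order turned for H3K4me1 at 4 h (6775 gained, 7380 lost) and for H3K4me3 at 1 h (1414 and 1398), and it did so with equal numbers taken by −log10 p (9053 and 9657, and 1602 and 1584). It also turned for H3K27me3 at 1 h among peaks with a −log10 q of at least 5 (5584 and 5617). Most counts moved under that threshold: at 4 h H3K4me1 gained 19194 and lost 16275 peaks, and H3K27me3 gained 6612. The deposited q values of overlapping broad peaks correlated between LPS and untreated lists with a Spearman rho of 0.0564 to 0.433. Counts under a threshold on them are therefore not a check on strong peaks, and which peaks it removes was not tested further. Equal numbers by −log10 p also rest on deposited values of these lists, so they are no check on strong peaks either.

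The widest gained and lost peaks are described by mm9 position, since no gene annotation of that build was used here. The widest H3K27ac peak gained at 4 h spanned 23326 bp on chromosome 16 (84698776 to 84722101). There H3K4me1 peaks covered 11.3% of the length in untreated cells and 63.1% at 4 h, H3K4me3 peaks 5.54% and 32.5%, and H3K36me3 peaks 19.2% and 73.6%, while H3K27me3 peaks covered 19.5% before LPS and none at 4 h. The widest H3K4me3 gain at 4 h lay on chromosome 2 (129130597 to 129137266), where H3K27ac covered 50.0% in untreated cells, 60.1% at 1 h and all of it at 4 h. The widest H3K27ac gain at 1 h, on chromosome 3 (135327373 to 135336164, 8792 bp), was fully covered by H3K27ac at 4 h as well. The widest H3K27ac loss was the same peak at both times, 6655 bp on chromosome 8 (58788204 to 58794858), which kept H3K4me1 over 88.3% of its length at 1 h and 87.7% at 4 h. The widest H3K36me2 loss, on chromosome 16 (55823381 to 55834843), was also shared by both times, and there H3K27ac covered 3.38% in untreated cells and 58.1% at 4 h. H3K79me2 was gained on chromosome 6 at 1 h (97896534 to 97904201) and at 4 h (97898156 to 97905715), within H3K36me3 that covered both peaks entirely in untreated cells. The widest H3K27me3 loss at 1 h, on chromosome 1 (166129254 to 166153930, 24677 bp), was covered again over 93.5% of its length at 4 h. The widest H3K36me3 gain at 4 h, on chromosome 2 (157274135 to 157296321, 22187 bp), held H3K27ac over 6.25% in untreated cells, 28.3% at 1 h and 18.3% at 4 h.

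H3K4me1 regions without H3K4me3, the usual chromatin definition of an enhancer, fell into a few common combinations of other marks. Untreated cells had 43936 such distal regions, of which 51.9% (51.4 to 52.3) carried H3K36me2, 27.2% H3K36me3, 24.3% H3K27ac, 17.7% H3K27me3 and 12.2% H3K79me2. For peaks with a −log10 q of at least 5 the order was another: of 24176 regions, 5457 carried H3K27ac, 4093 H3K36me3, 2536 H3K79me2, 1028 H3K36me2 and 529 H3K27me3. That threshold keeps 81.9% of H3K27ac peaks but 9.02% of H3K36me2 and 12.4% of H3K27me3 peaks. The order therefore also follows how unequally the lists were cut. The largest classes were those with none of these 5 marks (9252 regions), with H3K36me2 alone (7908), with H3K27me3 alone (6461) and with H3K27ac and H3K36me2 together (4749). H3K27ac without any other mark was found in 765 regions. PU.1 lay in 91.8% (91.0 to 92.6) of the regions with H3K27ac and H3K36me2 and in 87.5% of those with H3K27ac alone. It lay in 59.8% of those with none of the 5 marks, 51.6% of those with H3K36me2 alone, 55.2% of those with H3K27me3 alone, 42.9% of those with H3K36me3 alone and 35.7% of those with H3K36me2 and H3K79me2. Regions with H3K27ac and H3K36me2 were also wide, with a median of 3039 bp against 870 bp for those with none of the marks, but those with H3K36me2 and H3K79me2, at 1663 bp, had PU.1 less often than those with none. After LPS there were 43917 distal regions at 1 h and 50326 at 4 h. H3K27ac lay in 21.5% (21.1 to 21.9) of them at 1 h and 25.6% (25.2 to 26.0) at 4 h, and H3K27me3 in 17.6% and 22.7%. The class with H3K27me3 alone held 9190 regions at 4 h.

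The overlap of whole lists shows which marks share territory. In untreated cells, H3K4me3 and H3K27ac shared 32.3 Mb, 24.7 times the mean of 1000 shifts of one list along the chromosomes (log2 ratio 4.63). H3K4me1 shared 71.0 Mb with H3K27ac (log2 3.45), 98.2 Mb with H3K36me2 (2.21) and 58.3 Mb with H3K79me2 (2.89). H3K27me3 peaks had little overlap with marks of transcribed or active chromatin: they shared 0.374 Mb with H3K36me3 (log2 −6.60), 0.183 Mb with H3K79me2 (−6.35), 0.549 Mb with H3K27ac (−4.49) and 3.40 Mb with H3K36me2 (−3.58). Among the histone marks, H3K4me1 met H3K27me3 over the greatest length, at 10.7 Mb, still below every shift (−1.41). H3K4me3 was below every shift with H3K36me3 (−0.85) and, in untreated cells, with H3K36me2 (−0.34). The H3K4me3 and H3K36me2 value lay within the shifts at 1 h (0.04) and above all of them at 4 h (0.33), and in untreated cells it was −0.18, no longer beyond the shifts, for peaks with a −log10 q of at least 5. Of the 28 pairs in untreated cells, 18 lay above and 9 below all 1000 shifts. The remaining pair was PU.1 with H3K36me3, at a log2 ratio of 0.17.

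**Figure D2:**
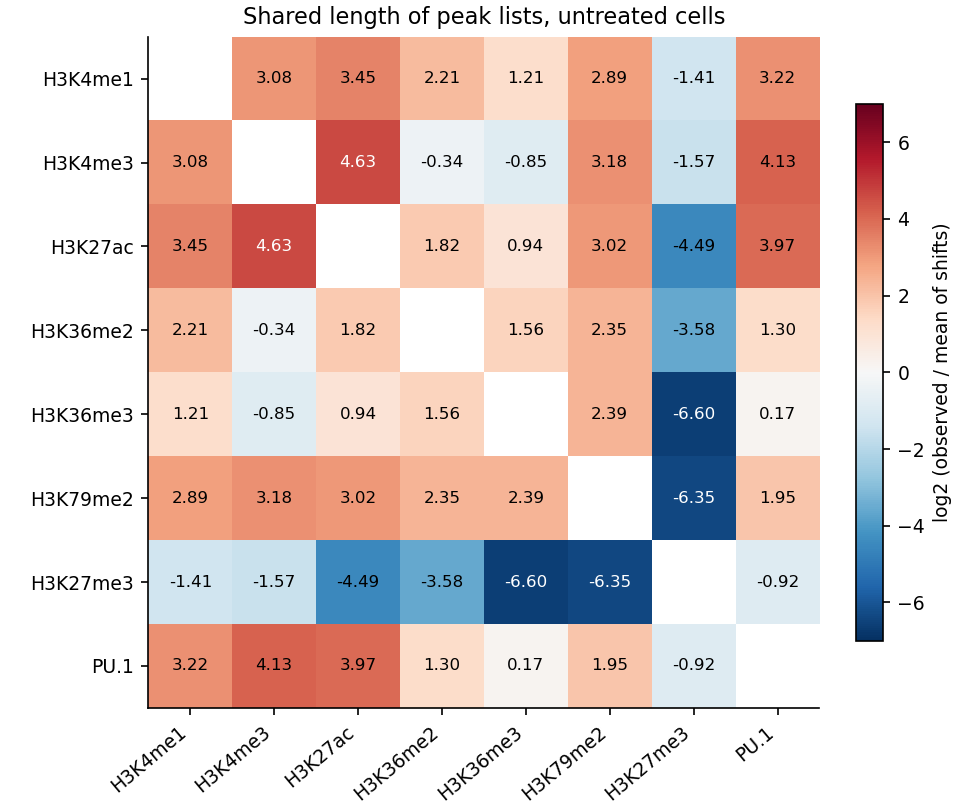
Shared length of each pair of peak lists in untreated cells, as the log2 ratio of the observed length to the mean of 1000 shifts along the chromosomes; red is above and blue below the shifts. H3K4me3 with H3K27ac is highest at 4.63 and H3K36me3 with H3K27me3 lowest at −6.60.

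PU.1 was bound mostly where H3K4me1 lay. Of 99565 PU.1 peaks, 69.6% (69.3 to 69.9) overlapped H3K4me1, 45.2% H3K27ac, 31.4% H3K36me2, 24.97% H3K4me3 and 10.8% H3K27me3, and 14.1% overlapped none of the 7 marks. With only peaks of a −log10 q of at least 5, those in none of the marks went from 14048 to 28310, and those in H3K4me1 without H3K4me3 from 49720 to 27673. By length shared, PU.1 was at 17.5 times the shifted lists with H3K4me3, 15.7 times with H3K27ac, 9.31 times with H3K4me1 and 0.530 times with H3K27me3. PU.1 peaks in H3K27ac had a median fold enrichment of 8.41 and the rest 5.36, in the authors' values. Those outside both H3K4me1 and H3K4me3 had a median of 4.91. The strongest PU.1 peak, at a fold enrichment of 79.3, lay on chromosome 19 (8093925 to 8095541), within H3K27ac and with H3K4me3 over 87.1% of its length. The next were on chromosome 15 (63994638 to 63995333), chromosome 6 (52792308 to 52793345) and chromosome 7 (3849521 to 3850320 and 90958080 to 90959348). H3K4me1 covered each of these 5 peaks entirely in untreated cells, and H3K4me3 was absent from all but the strongest.

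Distal H3K4me1 regions that appeared after LPS differed from those already present. At 4 h, 10376 distal regions were gained, and H3K27me3 lay in 35.9% (34.95 to 36.8) of them, against 19.9% on average in 1000 draws of kept regions matched for width and fold enrichment. PU.1 in untreated cells lay in 22.2% of the gained regions and 46.3% of the matched ones, and H3K36me2 in 26.0% and 47.9%. H3K27me3 already lay in 32.8% of the gained regions before LPS, and in 18.2% of the matched ones. Of the 4359 regions gained at 1 h, H3K27me3 lay in 33.7% (matched 16.7%), PU.1 in 29.8% (44.6%) and H3K36me2 in 23.0% (43.8%). Each of these values lay outside all 1000 draws. At positions shifted 1000 times along the chromosomes, the regions gained at 4 h had PU.1 in 5.02% on average (highest 5.94%). For H3K36me2 the shifted share was 15.2% on average (highest 17.0%). These gained regions thus had PU.1 and H3K36me2 less often than matched kept regions but more often than shifted positions. The lower PU.1 share is not particular to gains. In a comparison chosen later, lost regions also had PU.1 less often than matched kept ones, at 28.3% and 42.6% at 4 h and 28.65% and 45.5% at 1 h. For H3K27me3 and H3K36me2 the lost regions differed from matched ones in the opposite direction to the gains. Among peaks with a −log10 q of at least 5, the excess of H3K27me3 was 0.166 percentage points at 1 h, within the draws, and 0.576 at 4 h. That threshold keeps 12.2% of H3K27me3 peaks at 1 h and 11.7% at 4 h. Few regions of either kind can then carry the mark, so these points are not comparable with those of the full lists. H3K27ac was in 9.09% of the regions gained at 4 h and 8.24% of the matched ones, a difference of 0.845 percentage points that became −0.742 when only peaks of at least 1 kb were used and −0.523 with a −log10 q of at least 5. In untreated cells H3K27ac had lain in 0.492% of these gained regions and 7.29% of the matched ones. The matched regions were chosen for having H3K4me1 in untreated cells and the gains for lacking it.

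**Figure D3:**
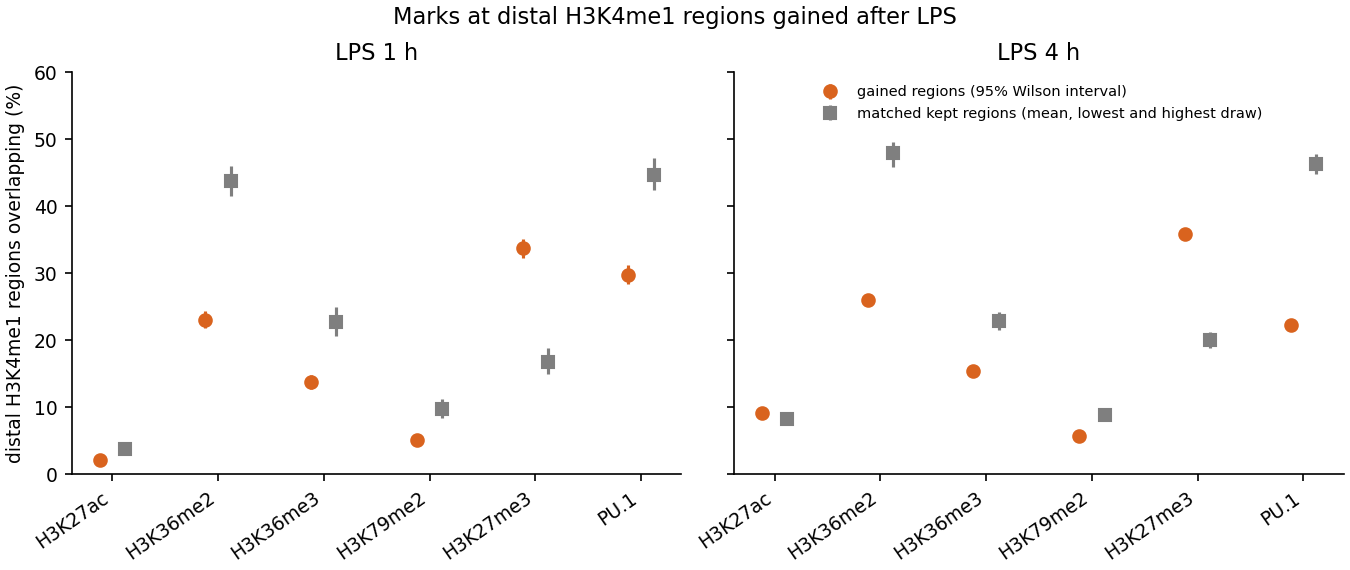
Share of distal H3K4me1 regions gained after LPS (circles, 95% Wilson interval) and of matched kept regions (squares, mean with lowest and highest of 1000 draws) that overlap each mark, in percent, at 1 h (left) and 4 h (right). At 4 h, H3K27me3 was in 35.9% of the gained regions and PU.1 in 22.2%.

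The 5 widest distal regions that gained both H3K4me1 and H3K27ac at 4 h lay on chromosomes 15, 16, 8, 5 and 1. The first, on chromosome 15 (6627333 to 6636939, 9607 bp), was covered entirely by H3K27me3 in untreated cells and over 86.1% of its length at 4 h. The region on chromosome 5 (32732165 to 32738344) had H3K27me3 over 79.4% of its length in untreated cells and 88.8% at 4 h, together with H3K27ac over 81.2% at 4 h. The region on chromosome 16 (84640840 to 84648876, 8037 bp) had no H3K27me3 peak and was covered entirely by H3K27ac at 4 h. Those on chromosome 8 (64035962 to 64042243) and chromosome 1 (16192764 to 16198171) had H3K27ac over 35.9% and 16.0% of their length at 4 h.

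Changes of different marks fell together at some places, and each mark is a separate immunoprecipitation. Where an H3K4me1 change met an H3K27ac change at 4 h, 959 pairs gained both and 48 lost both. In 28 pairs H3K4me1 was gained and H3K27ac lost, and in 43 the reverse, a log2 odds ratio of 5.23 against a highest value of 1.20 over 1000 permutations. H3K4me3 and H3K27ac had 232 joint gains and 89 joint losses at 4 h (log2 odds ratio 3.56), and H3K27ac and H3K36me2 had 449 and 41 (1.47). H3K36me3 and H3K79me2, both marks of transcribed genes, were at 2.15, which became 0.09 for peaks with a −log10 q of at least 5. H3K36me2 and H3K36me3 were at −2.53 at 4 h, below every permutation: 81 pairs gained both, 81 gained H3K36me2 and lost H3K36me3, 37 did the reverse and 6 lost both. That value became 0.14 for peaks with a −log10 q of at least 5. At 1 h the log2 odds ratio of H3K4me1 and H3K27ac was 2.94, with 78 joint gains and 88 joint losses, and became 0.08 under the same threshold. That of H3K4me3 and H3K27ac at 1 h was −0.16, within the permutations, and became 2.59 for peaks of at least 1 kb. Marks that shared little length also changed together at 1 h. H3K4me1 with H3K27me3 was at 2.57 and H3K36me2 with H3K27me3 at 1.73, both above every permutation. At 4 h these were 0.93, within the central 95% of permutations, and 1.08, above it. Agreement was thus not limited to marks of active chromatin, and sources of difference shared by lists of a condition were not tested. Deposited q values agreed less between lists than widths did, so the values under a −log10 q threshold are no check on strong peaks. At 4 h, 8 of the 21 pairs of marks lay above and 2 below the central 95% of permutations. Whether the lists of a condition share an input library is not given in the sources used here.

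Regions gained at 1 h were often still present at 4 h. H3K27ac kept 77.8% (76.2 to 79.4) of its 2613 gains, H3K36me2 69.7%, H3K4me1 67.6%, H3K27me3 64.6%, H3K4me3 54.4%, H3K79me2 49.0% and H3K36me3 40.9%. Matched 1 h peaks that had been present in untreated cells were in the 4 h list in 91.3% of cases for H3K27ac, 89.5% for H3K36me2, 89.9% for H3K4me1 and 69.3% for H3K36me3, and the gained share lay below all 1000 draws for each mark. Those matched peaks had been called in 2 lists and the gains in 1, and strength could not be matched, so a lower share is expected from the selection. Of the peaks lost at 1 h, 61.3% of those of H3K36me2, 58.2% of those of H3K4me1, 43.1% of those of H3K27ac and 33.9% of those of H3K36me3 were back at 4 h. No matched value was computed for these shares. A peak missed in the single 1 h library would also be back, so they do not show that a loss was reversed.

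Flavopiridol before LPS asks whether gains need transcription elongation. Of the 11004 H3K4me1 peaks gained at 4 h, 25.1% (24.3 to 25.9) were called after flavopiridol then LPS, and 28.3% (27.5 to 29.2) after flavopiridol alone. Kept peaks matched for width and fold enrichment were called in 46.3% and 60.3% of cases, and all kept peaks in 73.4% and 82.4%. Of the 11775 H3K36me2 gains, 37.2% were called after flavopiridol then LPS and 52.4% after flavopiridol alone, against 46.9% and 65.4% of matched kept peaks. The difference with flavopiridol alone was −0.0169 percentage points for H3K36me2 peaks with a −log10 q of at least 5. Only 114 peaks of that flavopiridol list pass this threshold. Almost no gained or kept peak could be called there, so this value does not weaken the difference. Kept peaks were also called in untreated cells and gains were not, so lower shares of gains are expected in part from the selection. Gains called with flavopiridol then LPS and not with flavopiridol alone numbered 912 for H3K4me1 (8.29%, matched 5.39%) and 718 for H3K36me2 (6.10%, matched 3.96%), above every draw. Fewer gains than matched peaks were in the list of flavopiridol alone, so more of them could count here. For peaks with a −log10 q of at least 5 the differences were −0.159 and −0.0538 percentage points. The flavopiridol then LPS lists hold 2485 such peaks for H3K4me1 and 24 for H3K36me2, so these signs cannot be read as a reversal. For H3K4me1 peaks of at least 1 kb the difference was 0.265, within the draws. The wide gains on chromosome 15 (6627333 to 6636939) and chromosome 16 (84707342 to 84716505 and 84640840 to 84648876) had no H3K4me1 peak with flavopiridol then LPS. Gains on chromosome 11 (3103770 to 3110546 and 94944688 to 94950214) and on chromosome 1 (16192764 to 16198171) overlapped one over 18.7%, 10.7% and 23.3% of their length. For H3K36me2, the widest gains absent with flavopiridol then LPS lay on chromosome 3 (126935452 to 126946660), chromosome 12 (120415411 to 120426237) and chromosome 4 (52486253 to 52496878). The widest that overlapped an H3K36me2 peak there lay on the X chromosome (136390611 to 136404334, 2.15% of the length), chromosome 13 (94950259 to 94961467, 43.9%) and chromosome 14 (26379031 to 26390077, 49.1%).

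**Figure D4:**
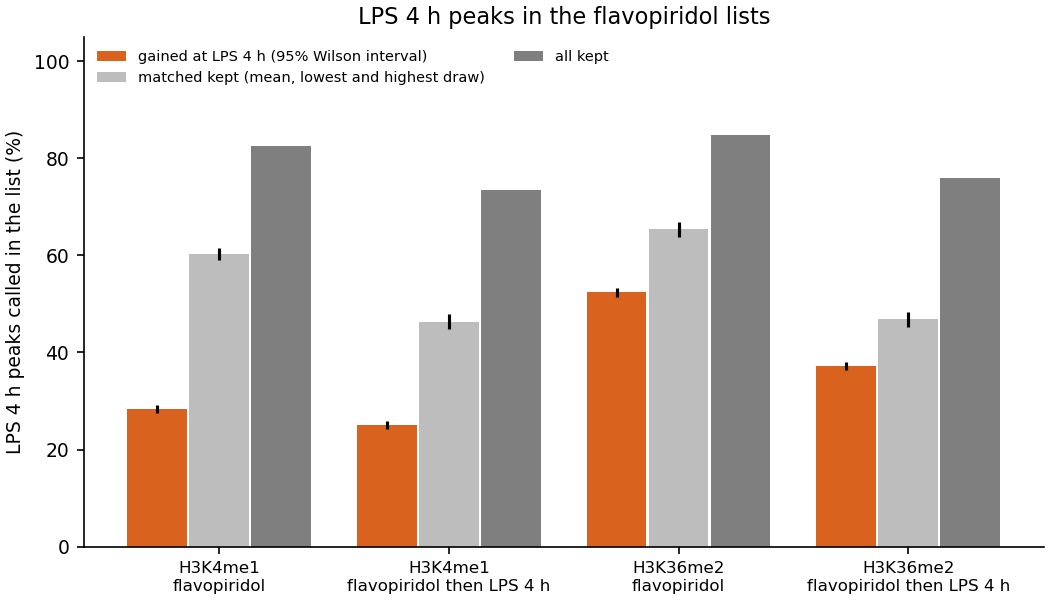
Share of LPS 4 h peaks, in percent, called in the flavopiridol lists of the same mark, for peaks gained at 4 h (orange, 95% Wilson interval), matched kept peaks (light grey, mean with lowest and highest of 1000 draws) and all kept peaks (dark grey). For H3K4me1 after flavopiridol then LPS these shares were 25.1%, 46.3% and 73.4%.

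The flavopiridol lists differed as a whole from those without the drug. H3K4me1 covered 143.7 Mb with flavopiridol and 117.2 Mb with flavopiridol then LPS, with 13728 peaks lost against untreated cells and 24807 lost against LPS at 4 h. H3K36me2 covered 304.6 Mb with flavopiridol and 230.0 Mb when LPS followed, a loss of 16997 peaks and a gain of 6103 between those lists. Against untreated cells, flavopiridol alone gained 16637 and lost 9178 H3K36me2 peaks, an order that turned for peaks with a −log10 q of at least 5 (104 gained and 4578 lost). The share of peaks with a −log10 q of at least 5 was 12.8% with flavopiridol and 4.02% with flavopiridol then LPS for H3K4me1, against 54.4% in untreated cells, and 0.197% and 0.0390% for H3K36me2. Such peaks covered 14.9 and 3.33 Mb for H3K4me1 and 0.194 and 0.0355 Mb for H3K36me2. The 4 flavopiridol samples and the 3 H3K27me3 samples are numbered after all others in the series, and whether they were prepared separately is not given in the sources used here.

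The authors' segmentation divides the genome into 27 chromatin states in each of the untreated, 1 h and 4 h conditions, and each state number had the most similar mark profile under its own number in the other conditions. The 10 states in which H3K36me2 peaks covered at least 50% of the length in untreated cells held 278.8 Mb in untreated cells, 298.8 Mb at 1 h and 333.3 Mb at 4 h. State 1, with H3K36me2 peaks over 99.9% of its length and no other mark over 50% in those cells, held 65.3, 101.3 and 125.4 Mb. State 4 (H3K36me2 and H3K79me2) held 9.81, 18.5 and 18.4 Mb, and state 3, an enhancer state with H3K4me1, H3K27ac and H3K36me2, 7.30, 6.90 and 10.5 Mb. State 17, the enhancer state with H3K4me1 and H3K27ac in which PU.1 peaks covered 51.0% of the length, held 17.95, 11.6 and 14.1 Mb. State 11 (H3K36me2, H3K36me3 and H3K79me2) held 14.3, 10.9 and 9.93 Mb, and 5.79 Mb of it was in state 4 at 4 h. Of state 26, where H3K36me2 peaks covered 64.5% of the length, 53.1 Mb was in state 1 at 4 h. State 19 (H3K27me3) held 286.4, 344.5 and 261.0 Mb, whereas H3K27me3 peaks covered most at 4 h. Over all states, 322.4 Mb (12.2%) carried another number at 4 h than in untreated cells, 291.1 Mb did at 1 h, and 301.5 Mb differed between 1 h and 4 h.

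**Figure D5:**
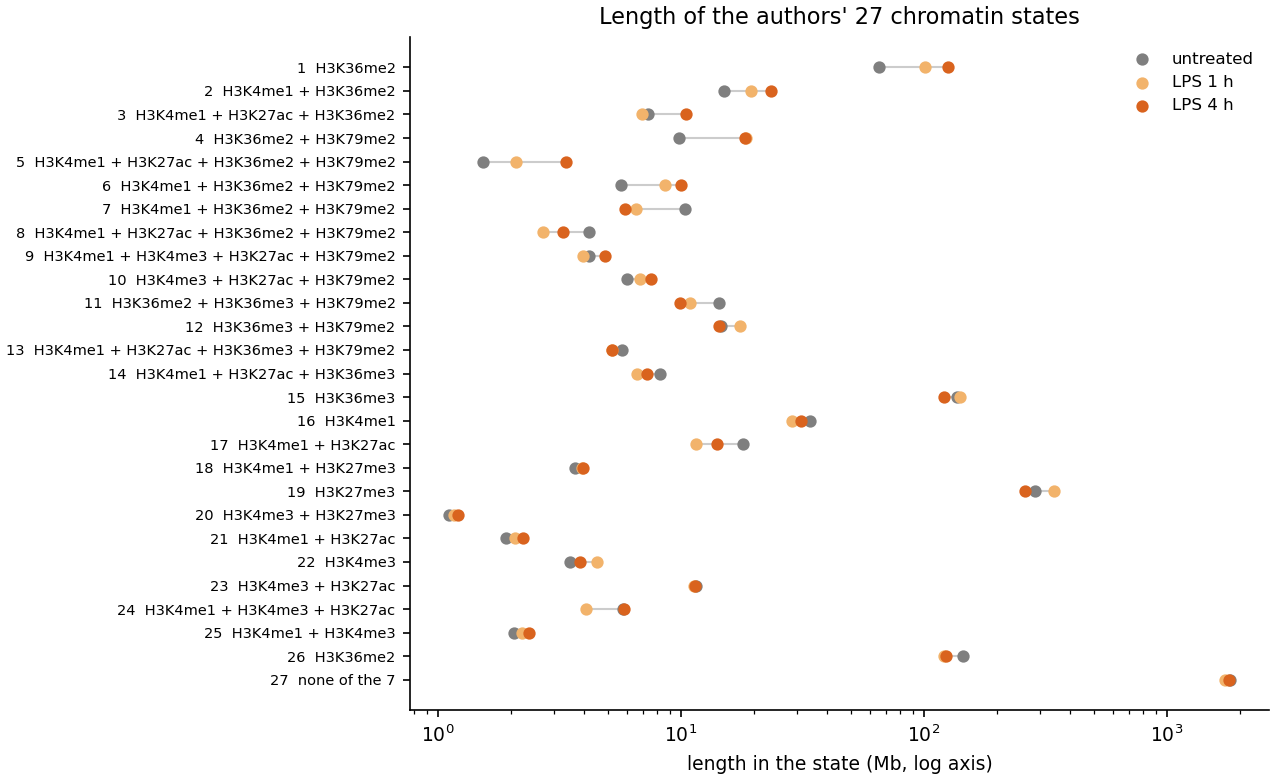
Length in each of the authors' 27 chromatin states, in Mb on a log axis, in untreated cells (grey), at 1 h (light orange) and at 4 h (dark orange) of LPS; marks whose peaks cover at least 50% of a state's length in untreated cells are named. State 1 held 65.3 Mb in untreated cells and 125.4 Mb at 4 h, and state 17 held 17.95 and 14.1 Mb.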

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

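The tests of weaker detection in untreated cells, of LPS treatment, of lower detection with flavopiridol and of blocking by flavopiridol were chosen only after the result was seen, and the restriction to peaks of at least 1 kb was also added then. The values below stand out because the covered length of a mark with LPS differed from that without LPS in opposite directions in different conditions. Each difference is between single libraries and was not tested, so it is not shown to be an effect of LPS. Without flavopiridol, the H3K36me2 length at LPS 4 h differed from that without LPS by 67.7 Mb, and with flavopiridol by −74.6 Mb. For H3K4me1 these differences were 8.25 and −26.5 Mb. Between 1 h and 4 h of LPS, the change from untreated cells was −15.8 and 8.25 Mb for H3K4me1, and −0.371 and 3.09 Mb for H3K4me3. It was −10.5 and 7.14 Mb for H3K27ac, and 2.29 and −5.96 Mb for H3K36me3.

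H3K36me2 peaks covered more of the genome after LPS than before. Weaker detection in the untreated library stays open: 52.4% of the H3K36me2 peaks gained at 4 h were called with flavopiridol alone, without LPS, −13.1 percentage points from matched kept peaks (65.4%) and below every draw. Strength could not be matched, and kept peaks were chosen for being called in untreated cells. The difference was −0.0169 for peaks with a −log10 q of at least 5, but only 114 flavopiridol peaks pass that threshold, so this value cannot decide. An earlier comparison with shifted positions, where the highest of 1000 shifts was 16.5%, was replaced after its result was seen, since any peak in H3K36me2 domains would pass it. Of the peaks lost at 4 h, 51.8% were called there. With flavopiridol, the change in covered length on LPS was −74.6 Mb, so no rise was seen there. In the lists of flavopiridol alone and of flavopiridol then LPS, 0.197% and 0.0390% of H3K36me2 peaks had a −log10 q of at least 5. The time since the drug may also differ between them, so this value does not decide on LPS treatment. LPS treatment still cannot be told apart from detection here, since flavopiridol acts on transcription, each condition is 1 library, and H3K36me2 gains coincided with H3K27ac gains (log2 odds ratio 1.47). They also coincided with H3K27me3 gains (1.08), so this coincidence does not decide on LPS treatment either. Both explanations stay open.

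Distal H3K4me1 regions gained at 4 h of LPS overlapped H3K27me3 more often than matched kept regions (35.9% and 19.9%) and PU.1 less often (22.2% and 46.3%). Regions lost at 4 h also had PU.1 less often than matched ones (28.3% and 42.6%), but H3K27me3 was not more frequent there (18.1% and 22.0%). Peaks called at random places along whole chromosomes are argued against, since 9.09% of the gained regions had H3K27ac, above the highest of 1000 shifts, 5.55%. Matched kept regions had it in 8.24%. The PU.1 share of the gained regions, 22.2%, was also above its highest shift, 5.94%. Peaks scattered only over chromatin rich in marks would pass these shifts too, and they are not argued against. Among gained regions of at least 1 kb the H3K27me3 share exceeded matched regions by 17.9 percentage points at 4 h (35.6% and 17.7%, highest draw 19.2%). The prediction written before this test counts that against marginal peaks near the calling threshold, although the 1 kb restriction was added after results were seen. Width correlated with fold enrichment at only 0.0718, but the fold values agreed less between lists than widths did. Whether width measures closeness to the threshold is therefore not known, and marginal peaks stay open. For peaks with a −log10 q of at least 5 the excess was 0.576 points at 4 h and 0.166 at 1 h, the latter within the draws, and the PU.1 difference at 4 h was −9.06. Only 11.7% of H3K27me3 peaks at 4 h and 12.2% at 1 h pass that threshold, so these H3K27me3 values cannot be set against 17.9 points. The reading of the 1 kb test was changed after its result was seen. A hypothesis that LPS places H3K4me1 at regions with H3K27me3 stays open and may be followed up, with the limit that the strength of each peak could not be matched. No test separates cells with both marks from a mixture of cells.

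H3K4me1 peaks gained at 4 h were largely missing after flavopiridol then LPS. For gained peaks the ratio of the share in the flavopiridol then LPS list to that in the flavopiridol list was 0.887 (0.860 to 0.913). It was 0.681 (0.646 to 0.715) for lost peaks, a gap set beforehand to count against chance absence from the untreated list. But gained and lost peaks were not matched (median width 642 and 556 bp), and the intervals cover counting error only. The shares were 46.3% and 60.3% for matched kept peaks and 73.4% and 82.4% for all kept peaks, so the ratio moves with the peaks chosen. Chance absence therefore stays open. Lower detection in the flavopiridol libraries stays open: gained peaks were −21.2 percentage points from matched kept peaks, more than any draw, but strength could not be matched, kept peaks were chosen for being called in untreated cells, and the reading of this test was changed after its result was seen. Blocking by flavopiridol stays open too, with 25.1% of the gains called after flavopiridol then LPS and 28.3% after flavopiridol alone. These explanations cannot be told apart, since each condition is 1 library and the strength of each peak could not be matched.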

How the results depend on the processing

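The alternatives were fixed before the data were examined, except peaks of at least 1 kb and equal numbers of peaks by width, which were chosen only after the result was seen. Including all sequences or merging peaks within 1 kb left each of 144 values on its side. The smallest gap between histone peaks was 1081 bp, so merging changed none of their lists. Matching on width only left 18 values on their side, and requiring no H3K4me3 within 2 kb left 21. The order of gained and lost peaks was kept under 7 alternatives in 16 of 20 comparisons. Among these alternatives, merging could not change the order. Including all sequences added few peaks, as from 65547 to 65562 for H3K4me1 in untreated cells. Those by −log10 q and −log10 p are no check on strong peaks. The alternatives for gene lists were not run, since no annotation of the build was used here, and at least 50% coverage has no meaning for shared length. No paired analysis was possible because each condition has 1 library per mark. Read depth is unknown and limits how far a missing peak can be read as absence. Values of the main results are given below where they moved, and the cause was not tested.

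With a −log10 q of at least 5, the lists were shorter, and unequally so. In untreated cells 81.9% of H3K27ac peaks passed, but 9.02% of H3K36me2 and 12.4% of H3K27me3 peaks. For H3K36me2, 114 peaks passed with flavopiridol and 24 with flavopiridol then LPS. Overlap shares with such short lists are small for any set of regions, so their differences cannot be set against those of the full lists. H3K4me1 gained 13642 and lost 18255 peaks at 1 h and gained 19194 and lost 16275 peaks at 4 h. H3K4me1 gained 4352 and lost 31592 peaks with flavopiridol against untreated cells and gained 1283 and lost 37636 peaks with flavopiridol then LPS against LPS. H3K4me1 gained 2045 and lost 8157 peaks with flavopiridol then LPS against flavopiridol. H3K4me3 gained 2411 and lost 2940 peaks at 1 h and gained 3401 and lost 2477 peaks at 4 h. H3K27ac gained 4835 peaks at 1 h and lost 6911 peaks at 4 h. H3K36me2 lost 2810 peaks at 1 h and gained 104 and lost 4578 peaks with flavopiridol against untreated cells. H3K36me2 gained 18 peaks with flavopiridol then LPS against LPS and gained 24 and lost 114 peaks with flavopiridol then LPS against flavopiridol. H3K36me3 gained 7026 and lost 5092 peaks at 1 h and gained 5768 and lost 7488 peaks at 4 h. H3K79me2 lost 2236 peaks at 1 h and lost 2237 peaks at 4 h. H3K27me3 gained 5584 and lost 5617 peaks at 1 h and gained 6612 peaks at 4 h. H3K4me1 covered 117 Mb in untreated cells, 93.0 Mb at 1 h, 118 Mb at 4 h, 14.9 Mb with flavopiridol and 3.33 Mb with flavopiridol then LPS. H3K36me2 covered 19.4 Mb in untreated cells, 66.4 Mb at 1 h, 113 Mb at 4 h, 0.194 Mb with flavopiridol and 0.0355 Mb with flavopiridol then LPS. H3K36me3 covered 148 Mb in untreated cells and 124 Mb at 4 h. H3K27me3 covered 40.3 Mb in untreated cells, 40.7 Mb at 1 h and 42.5 Mb at 4 h. Distal H3K4me1 regions numbered 24176 in untreated cells, 21584 at 1 h and 26797 at 4 h. Of the distal H3K4me1 regions of untreated cells, there were 5457 with H3K27ac, 1028 with H3K36me2, 4093 with H3K36me3, 2536 with H3K79me2, 529 with H3K27me3 and 14294 with PU.1. 27673 PU.1 peaks lay in H3K4me1 without H3K4me3 and 28310 PU.1 peaks lay in none of the 7 histone marks. The log2 ratio of shared length of H3K4me3 and H3K36me2 in untreated cells was −0.18, within the shifts. The H3K27me3 share of distal H3K4me1 regions gained at 1 h differed from matched regions by 0.166 percentage points. The H3K27ac share of distal H3K4me1 regions gained at 4 h differed from matched regions by −0.523 percentage points. For H3K4me1 gains at 4 h in the list of flavopiridol then LPS and not that of flavopiridol, the difference from matched peaks was −0.159 percentage points. For H3K36me2 gains at 4 h in the flavopiridol list, the difference from matched peaks was −0.0169 percentage points. For H3K36me2 gains at 4 h in the list of flavopiridol then LPS and not that of flavopiridol, the difference from matched peaks was −0.0538 percentage points. Gains and losses at 1 h had a log2 odds ratio of 0.0825 for H3K4me1 and H3K27ac, 0.0340 for H3K4me1 and H3K36me2, 0.21 for H3K4me1 and H3K27me3, 0.17 for H3K27ac and H3K36me2, −0.0340 for H3K36me2 and H3K36me3 and −0.26 for H3K36me3 and H3K79me2. For LPS at 4 h the log2 odds ratio of gains and losses was 0.12 for H3K4me1 and H3K36me2, 0.41 for H3K4me1 and H3K27me3, 0.14 for H3K36me2 and H3K36me3 and 0.0945 for H3K36me3 and H3K79me2.

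Requiring at least 50% of a peak to be covered raised counts of gained and lost peaks. H3K4me1 lost 11055 peaks at 1 h and lost 7145 peaks at 4 h. H3K4me1 lost 25338 peaks with flavopiridol against untreated cells and gained 10724 and lost 41908 peaks with flavopiridol then LPS against LPS. H3K4me1 gained 10679 and lost 23338 peaks with flavopiridol then LPS against flavopiridol. H3K27ac lost 6395 peaks at 4 h. H3K36me2 gained 16593 and lost 7542 peaks at 1 h and gained 19514 and lost 5167 peaks at 4 h. H3K36me2 lost 14472 peaks with flavopiridol against untreated cells and lost 26204 peaks with flavopiridol then LPS against LPS. H3K36me2 gained 11642 and lost 29399 peaks with flavopiridol then LPS against flavopiridol. H3K36me3 gained 5489 and lost 5091 peaks at 1 h and gained 5503 and lost 6812 peaks at 4 h. H3K79me2 gained 3402 and lost 1952 peaks at 1 h and gained 3983 and lost 1910 peaks at 4 h. H3K27me3 gained 19648 and lost 14950 peaks at 1 h and gained 31134 and lost 11260 peaks at 4 h. Of the distal H3K4me1 regions of untreated cells, there were 4899 with H3K27ac, 5148 with H3K27me3 and 5508 with PU.1. The H3K27ac share of distal H3K4me1 regions gained at 4 h differed from matched regions by 0.251 percentage points. Gains and losses at 1 h had a log2 odds ratio of 0.39 for H3K4me3 and H3K27ac and −0.0346 for H3K36me2 and H3K36me3.

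Equal numbers of peaks by −log10 p gave the values below, which rest on deposited values and are no check on strong peaks. H3K4me1 lost 9657 peaks at 4 h and gained 12918 peaks with flavopiridol then LPS against LPS. H3K27ac gained 4305 peaks at 1 h and lost 6991 peaks at 4 h. H3K27me3 lost 10283 peaks at 4 h. The H3K27ac share of distal H3K4me1 regions gained at 4 h differed from matched regions by 0.352 percentage points. Gains and losses at 1 h had a log2 odds ratio of 0.12 for H3K4me3 and H3K27ac. For LPS at 4 h the log2 odds ratio of gains and losses was 0.47 for H3K4me1 and H3K36me2 and 0.80 for H3K4me1 and H3K27me3.

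Restricting lists to peaks of at least 1 kb gave these values. H3K4me1 gained 7247 peaks at 4 h and gained 4521 peaks with flavopiridol against untreated cells. H3K4me1 gained 3527 peaks with flavopiridol then LPS against LPS and gained 3947 peaks with flavopiridol then LPS against flavopiridol. H3K4me3 gained 643 and lost 789 peaks at 1 h and gained 1254 and lost 614 peaks at 4 h. H3K27ac gained 4699 peaks at 4 h. H3K36me2 lost 2858 peaks at 1 h and lost 1859 peaks at 4 h. H3K36me2 gained 4717 peaks with flavopiridol then LPS against LPS and gained 3849 peaks with flavopiridol then LPS against flavopiridol. H3K36me3 lost 2046 peaks at 1 h. H3K79me2 lost 772 peaks at 1 h and lost 746 peaks at 4 h. H3K27me3 lost 5999 peaks at 1 h and lost 4053 peaks at 4 h. The H3K27ac share of distal H3K4me1 regions gained at 4 h differed from matched regions by −0.742 percentage points. For H3K4me1 gains at 4 h in the list of flavopiridol then LPS and not that of flavopiridol, the difference from matched peaks was 0.265 percentage points. Gains and losses at 1 h had a log2 odds ratio of 0.72 for H3K4me1 and H3K27me3, 2.59 for H3K4me3 and H3K27ac and 0.52 for H3K36me3 and H3K79me2. For LPS at 4 h the log2 odds ratio of gains and losses was 0.57 for H3K4me1 and H3K36me2 and −0.14 for H3K4me1 and H3K27me3.

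Equal numbers of peaks by width gave these values. H3K4me1 gained 6775 and lost 7380 peaks at 4 h. H3K36me2 gained 3680 peaks with flavopiridol then LPS against LPS and gained 3936 peaks with flavopiridol then LPS against flavopiridol. Gains and losses at 1 h had a log2 odds ratio of 0.59 for H3K4me1 and H3K36me2, 0.30 for H3K4me3 and H3K27ac and 0.93 for H3K36me3 and H3K79me2. For LPS at 4 h the log2 odds ratio of gains and losses was 0.47 for H3K4me1 and H3K36me2.

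Counting base pairs in place of peaks kept the order of gained and lost in 14 of 14 comparisons with untreated cells, while the 28 shares all moved. For H3K27ac, 13.5% of the length was gained and 24.4% lost at 1 h, and 25.05% gained and 18.6% lost at 4 h.

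With segments of at least 400 bp, 75 state lengths stayed within their limits and 6 moved. State 21 held 1.10 Mb in untreated cells, 1.27 Mb at 1 h and 1.41 Mb at 4 h. State 25 held 1.24 Mb in untreated cells, 1.28 Mb at 1 h and 1.46 Mb at 4 h.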

Other observations

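The comparisons of lost regions, the splits by H3K27ac and the comparison of strength with length were chosen only after the result was seen. Distal H3K4me1 regions lost after LPS differed from matched kept ones in the marks they carried. Of the 3915 distal regions lost at 4 h, 30.6% had H3K36me3 in untreated cells, against 19.3% of matched kept regions, and 12.5% had H3K79me2, against 6.10%. H3K36me2 lay in 40.5% of them and in 32.6% of the matched ones, and H3K27me3 in 18.1% and 22.0%. PU.1 lay in 28.3% of the lost regions and in 42.6% of the matched ones. Each of these shares lay outside all 1000 draws.

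H3K27ac came and went on distal H3K4me1 regions present both before and after LPS. Of 40021 such regions at 4 h, 8172 had H3K27ac at both times, 4101 gained it, 2447 lost it and 25301 had it at neither time. PU.1 in untreated cells lay in 91.6% of those with H3K27ac at both times, 62.9% of those that gained it, 81.5% of those that lost it and 53.7% of those without. At 1 h, 1498 gained and 3408 lost H3K27ac. Of the 883 distal regions that gained both H3K4me1 and H3K27ac at 4 h, 15.7% had PU.1 in untreated cells, against 58.6% of matched regions. Another set, 4082 distal regions of the 4 h list that kept H3K4me1, overlapped a gained H3K27ac peak, and 361 of them had also overlapped H3K27ac in untreated cells. In this set 68.1% had PU.1 (matched 73.7%), 79.7% had H3K4me1 with flavopiridol (84.1%) and 68.3% had it with flavopiridol then LPS (74.9%). Each of these 4 h shares given with a matched value lay below all 1000 draws. In the 1663 such regions of the 1 h list that kept H3K4me1 and met an H3K27ac gain, the flavopiridol shares went the other way. H3K4me1 lay in 88.3% with flavopiridol (matched 85.6%) and 79.3% with flavopiridol then LPS (76.0%), both above all draws. PU.1 lay in 72.3% of them (matched 74.4%).

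By the rule fixed before the data were examined, which ranks broad peaks by deposited fold enrichment, the leading H3K27ac gain at 4 h was 744 bp wide on chromosome 6 (95825160 to 95825903), within H3K4me1 in untreated cells. The leading H3K27ac loss at 4 h was 1243 bp wide on chromosome 12 (9135122 to 9136364), with PU.1 over 67.9% of it. The leading H3K4me1 gain at 4 h was 954 bp wide on chromosome 5 (104282423 to 104283376), within H3K36me3, and the leading H3K36me2 gain was 1034 bp wide on chromosome 2 (38882745 to 38883778). Across 14 comparisons of a mark after LPS with untreated cells, the share of peaks with a −log10 q of at least 5 and the covered length moved in the same direction in 10, which were 6 of 7 at 1 h and 4 of 7 at 4 h.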
